A study of Homo sapiens with 29 samples.

How the data were processed

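Fragment lengths were measured by RICC-seq, a method in which gamma rays break DNA in clusters, so that the single-stranded fragments released between nearby breaks carry, in their length, information on which stretches of DNA lay close together in space. The series lists 29 human libraries; length data for 6 of them were analysed here, and the other 23, from 3 primary experiments, were not analysed here, nor was the ATAC-seq experiment. The 6 libraries came from 2 experiments. A size-selected experiment on BJ fibroblasts (an established skin fibroblast line, passages 18 to 20 per the labels) had 2 libraries from intact cells given 300 Gy, 1 from cells lysed and cleared of protein before 300 Gy, and 1 from intact cells given 0 Gy. A crosslinking experiment on BJ-5ta cells (the same line immortalised with telomerase) had 1 library from live cells and 1 from cells fixed with EGS, an amine-reactive crosslinker, and then 1% formaldehyde, both given 300 Gy. Per the labels' protocols, single-stranded fragments diffused out of agarose plugs, were ligated to adapters with random hexamer overhangs, amplified by PCR and cut from agarose gels before and after amplification.

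The deposited values are counts: whole numbers of read pairs at each fragment length, 1 table per library. Per the file headers, the authors made them with Picard's CollectInsertSizeMetrics, keeping pairs in forward-reverse orientation and a histogram width of 1000 nt. Per the file headers the input names carry a duplicate-removal suffix in all 6 libraries, 2 further suffixes in the live and crosslinked libraries only, and a subsampling suffix in the live library only; what these steps were is not given in the sources used here. The submitters' processing notes name Bowtie2, SAMtools 0.1.19, bedtools 2.20.1, Picard 1.117 and the hg19 build, without saying how each was used. Because the 2 experiments were filtered differently, shares were compared only within an experiment, apart from 1 ratio of short fragments in the closing section. Only the forward-reverse orientation was present, so a sum over all orientations, intended as an alternative, gave no value.

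All computations started from these deposited counts and used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The share of fragments in a length window was given with an exact (Clopper-Pearson) 95% binomial interval. For a local contrast, the mean of log2(count + 0.5) over a feature window minus the mean over a flank on each side, both flanks weighted equally, was computed within a library; a trend that is straight on the log scale, such as a gradual loss of long fragments on a gel, cancels in it for the one-repeat, between and two-repeat features, whose flanks are centred on the window, but leaves a residue for the gyre and three-repeat features, whose flanks are centred 1 and 5 nt longer than the window. The 4 windows were set from nucleosome geometry before the data were examined, and their names say only which length was expected there. The gyre window was 68 to 88 nt, with flanks at 50 to 60 and 98 to 108 nt. The one-repeat window was 167 to 197 nt, with flanks at 127 to 142 and 222 to 237 nt. The between window was 265 to 295 nt, with flanks at 230 to 245 and 315 to 330 nt. The two-repeat window was 350 to 390 nt, with flanks at 315 to 330 and 410 to 425 nt. A three-repeat window of 530 to 580 nt, with flanks at 485 to 500 and 620 to 635 nt, was added after the profiles had been seen. A feature was left out where any library of the comparison averaged under 20 fragments per nt in a window or flank. Differences of contrasts carry 95% intervals from 1000 Poisson redraws of the counts, and a difference was called where its interval excluded 0 and, for the size-selected libraries, both intact libraries lay on the same side of the control.

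Maxima were sought from 50 nt to the longest length at which the library still averaged 20 fragments per nt over 11 nt. The profile of log2(count + 0.5) was smoothed with a Gaussian of sigma 5 nt, and the same profile smoothed with sigma 40 nt was subtracted. A maximum was called at a prominence of at least 0.03 (log2) that was also at least 4 times its SD over 200 redraws. Helical periodicity was measured as the amplitude of a sine and cosine fitted at periods from 7 to 14 nt, with 10.3 nt as the period set beforehand, to the profile from 60 to 200 nt after subtracting a 21-nt running mean. Ratios of shares were taken in 10-nt bins. No genes are measured in these data. The features planned for naming were the 4 windows, the fixed length windows and at most the 8 most prominent maxima of each library. The three-repeat window and fine maxima inside the short peak were added after the profiles had been seen. On simulated histograms with 2 planted maxima of 0.3 (log2), 40 of 40 were recovered within 10 nt for the size-selected comparison and 40 of 40 for the crosslinking comparison. Intervals for the two-repeat difference covered the planted value in 20 and 19 of 20 simulations, and false maxima between 320 and 600 nt numbered 0 and 1 over the 20 unchanged profiles. The simulated depths were those of the lysed and live libraries. Lower maxima, and a depth as small as that of the 0 Gy library, were not simulated. Counts and intervals were both Poisson, so this coverage follows from the construction and does not bear on variation between libraries.

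Depth ranged from 11627 fragments in the 0 Gy library to 1264648 in intact replicate 1. Every condition except the size-selected intact cells had 1 library, and per the series description repeat libraries within an experiment are technical, so no p-value was computed between conditions. All intervals cover counting error only: PCR reads without molecular identifiers are not independent molecules, and differences between cultures, gels or ligations are not in them. Alternatives were narrower or shifted windows, summed counts, each intact library left out, other smoothing and prominence settings, another running mean and length range for the periodicity, a length range of 50 to 500 nt and, chosen after seeing the data, a lower depth floor and flanks weighted to the window centre.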

Results

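Single-stranded fragment lengths were compared in a size-selected experiment, in which long fragments were isolated from BJ fibroblasts, and in a crosslinking experiment in BJ-5ta cells. The size-selected libraries held 1264648 and 1052376 fragments of up to 1000 nt for intact cells given 300 Gy, 1043476 for lysed cells given 300 Gy and 11627 for intact cells given 0 Gy. The live and crosslinked libraries held 558215 and 531247 fragments. Median lengths were 452 and 408 nt in the 2 intact size-selected libraries, 454 nt in the lysed and 419 nt in the 0 Gy library, against 138 nt in the live and 139 nt in the crosslinked library.

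The first comparison asked how the length profile of DNA broken inside intact cells differed from that of DNA irradiated after its proteins had been removed. Intact irradiated cells had an excess of fragments at 350 to 390 nt, a length close to that of DNA spanning a pair of nucleosome repeats, that the lysed library had only to a small extent. The local contrast of this two-repeat feature over its flanks was 0.23 ± 0.01 (log2, mean ± SD, n = 2 technical libraries) in intact cells and 0.025 (95% interval 0.011 to 0.038) in lysed cells. The difference was 0.20 (0.19 to 0.22), or 1.15-fold, and was called. Maxima were called at 371 nt (SD over redraws 1.4 nt) in replicate 1 and at 375 nt (SD 3.3 nt) in replicate 2, while the lysed library had none called there: its highest point between 340 and 400 nt had a prominence of 0.0045, or 0.56 of its SD. The call in replicate 2 was lost with smoothing of 3 nt or a trend of 60 nt; that in replicate 1 was kept in all 4 other settings.

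**Figure D1:**
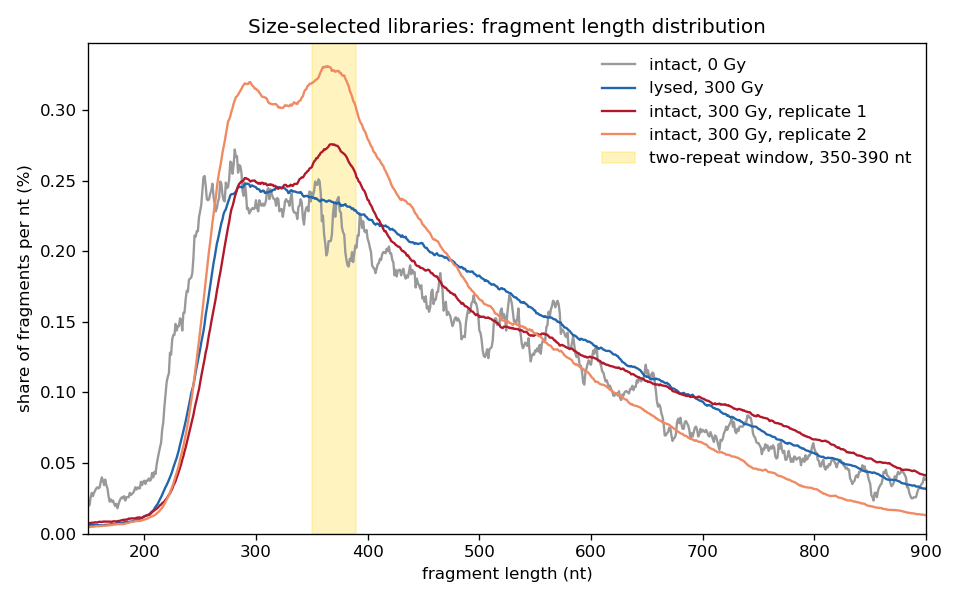
Share of fragments per nt (%, 11-nt running mean) against fragment length (nt) in the 4 size-selected libraries, 1 line each; the shaded band is the two-repeat window of 350 to 390 nt. Both intact 300 Gy lines rise to a maximum inside the band, the lysed line declines through it, and the 0 Gy line, from 11627 fragments, is uneven.

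The ratio of shares, intact mean over lysed, reached its highest value in the bin from 360 to 369 nt, at 1.28-fold (log2 0.36, 0.34 to 0.38; 0.22 and 0.49 in the 2 intact libraries taken singly). Fragments above 350 and up to 400 nt made up 14.5 ± 1.84% of the intact libraries (SD, n = 2) and 11.6% (11.6 to 11.7) of the lysed library. Above 500 and up to 700 nt the shares were 23.7 ± 1.68% and 27.1% (27.0 to 27.2). Shares sum to 100% in each library, so a higher share at one length lowers the others, and the 2 intact libraries themselves differed by up to 3.82-fold, at 990 to 999 nt. A chi-square test of homogeneity, which compares these libraries and not conditions, gave a statistic of 64.7 per degree of freedom between them, so they were counted as 2 libraries. After the broad trend was subtracted, their profiles from 300 to 700 nt correlated across lengths at r = 0.98. The r of each with the lysed library was 0.78 and 0.77. Lengths are not independent replicates. The start of the selected range still left detrended values of 0.36 and 0.37 at 300 nt in the intact libraries. At 371 nt these were 0.16 and 0.15, so that residue weighs heavily in r.

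The shorter features lay on or below the lower edge of the selected range, which rose steeply between 200 and 300 nt. The between feature, near 280 nt, had a contrast of 0.95 ± 0.10 in intact and 0.76 in lysed cells, a called difference of 0.19 (0.17 to 0.21) that was 0.12 without intact replicate 2. The log2 ratio of shares, intact mean over lysed, was -0.32 at 230 to 239 nt, in the shorter flank. It was 0.17 both at 280 to 289 nt, in the window, and at 310 to 319 nt, near the longer flank. The between difference thus came mostly from its shorter flank. At the one-repeat feature the contrasts were -0.75 ± 0.02 and -1.09, a called difference of 0.34 (0.26 to 0.44) that was 0.16 with the window and flanks set 10 nt longer. The same ratio was 0.13, 0.034 and 0.019 in the bins from 170 to 199 nt, but -0.44 and -0.32 in those from 220 to 239 nt. In the shorter flank it was -0.15 at 130 to 139 nt. In this mean, lower flanks thus made more of the one-repeat difference than a higher window did, but the 2 intact libraries did not share this. In replicate 1 the ratio was 0.32, 0.26 and 0.20 from 170 to 199 nt and 0.32 at 130 to 139 nt. There the window was higher and the shorter flank was not lower. In replicate 2 the ratio was -0.06, -0.19 and -0.17 from 170 to 199 nt and -0.63 at 130 to 139 nt. Fragments above 150 and up to 200 nt were only 0.41 ± 0.09% of the intact and 0.38% of the lysed library. The gyre feature, the distance between neighbouring turns of DNA on 1 nucleosome, was not called different: its contrast was 0.37 ± 0.04 in intact and 0.46 in lysed cells (difference -0.09, -0.22 to 0.04). Maxima were called at 83 and 82 nt in the intact libraries and at 82 nt in the lysed library. The maxima at 275 nt in intact replicate 1 and 264 nt in replicate 2, with one 1 nt longer than the latter in the lysed library, lay where the selected range began. Replicate 1 had a further maximum, at 560 nt with a prominence of 0.082, which was lost with smoothing of 3 or 8 nt and with a trend of 60 nt.

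The second comparison set the same intact libraries against cells that were not irradiated. The contrast of the unirradiated library at 350 to 390 nt was not distinguishable from 0 (0.0014, -0.14 to 0.14), and the difference from the intact libraries was 0.23 (0.09 to 0.37), or 1.17-fold, which was called. It was 0.10 with the window and flanks set 10 nt shorter. The ratio of shares, intact mean over 0 Gy, was highest in the bin from 360 to 369 nt, at 1.48-fold (log2 0.57, 0.38 to 0.75). The bin from 380 to 389 nt was close behind, at log2 0.55 (0.36 to 0.74). With 236 and 227 fragments of the 0 Gy library in these bins, the position of the highest ratio is not resolved. The between feature had a contrast of 0.31 without irradiation, 0.64 (0.48 to 0.77) lower than in intact irradiated cells. Its thinnest stretch averaged 20 fragments per nt in the 0 Gy library, the floor itself. The log2 ratio of shares, intact mean over 0 Gy, was -1.41 and -1.07 in the bins from 230 to 249 nt, at the shorter flank. From 270 to 299 nt, at the window, it ran only from 0.011 to 0.30. The difference thus came mostly from the 0 Gy library's higher share of fragments at that flank. The 0 Gy library held a higher share of short fragments. It was 6.12% (5.69 to 6.57) above 200 and up to 250 nt against 2.28 ± 0.19%, and 2.91% (2.61 to 3.23) from 50 to 100 nt against 0.32 ± 0.15%. In counts the 0 Gy library held fewer, with 711 and 338 fragments in these ranges. Intact replicate 1 held 27130 and 5417, and replicate 2 held 25469 and 2203. The called maxima of the 0 Gy library were at 72 and 162 nt, the latter lost with smoothing of 3 or 8 nt and with a trend of 60 nt. The gyre and one-repeat features averaged fewer than 20 fragments per nt in this library and were not compared; the two-repeat window held 25.4 fragments per nt in it, against 3395 in either intact library.

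**Figure D2:**
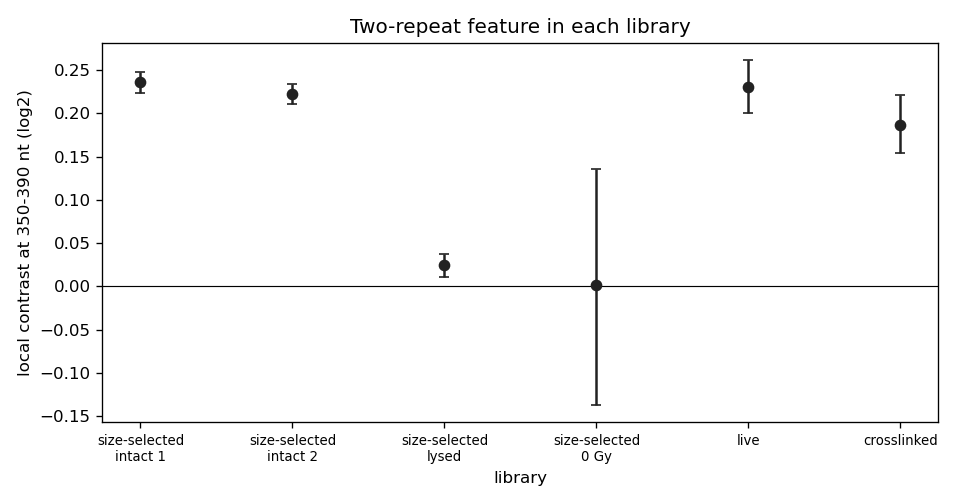
Local contrast of the two-repeat feature (log2 of the count at 350 to 390 nt over its flanks) in each of the 6 libraries; points are values and bars are 95% intervals from Poisson redraws. Intact, live and crosslinked irradiated libraries lie between 0.19 and 0.24, the lysed library at 0.025 and the 0 Gy library at 0.0014 with the widest interval.

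The third comparison asked whether fixing chromatin before irradiation changed the profile. Both libraries had the same features, a sharp short peak and a maximum near the length of 1 nucleosome repeat. The mode of the short peak, from counts without the trend subtracted, was 79 nt (95% interval 78 to 79) in live cells. In crosslinked cells it was 78 nt (78 to 78). Called like the other maxima, with the trend subtracted, this peak lay at 74 nt (SD 0.12 nt) in live and 75 nt (SD 0.37 nt) in crosslinked cells. Only these calls compare with the short maxima of the size-selected libraries. The one-repeat maximum was called at 178 nt (SD 0.68 nt) in live and 177 nt (SD 0.99 nt) in crosslinked cells. Live cells had another called maximum at 377 nt (SD 2.8 nt). In crosslinked cells the highest point from 340 to 400 nt, at 363 nt, had a prominence of 0.20, or 2.5 times its SD, and was not called, though with smoothing of 8 nt a maximum was called at 366 nt. A call at 687 nt in crosslinked cells had a prominence of 0.25, 4 times its SD of 0.061, and was lost with smoothing of 3 or 8 nt and with a trend of 60 nt. The detrended profiles of both libraries from 50 to 500 nt correlated across lengths at r = 0.98. The short peak dominates this r: detrended values in crosslinked and live cells were 3.21 and 2.88 at 75 nt. At 178 nt they were 0.22 and 0.24, so the r says little on the longer features.

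The libraries differed in their shortest and longest fragments. Fragments of 21 to 67 nt were 5.16% (5.10 to 5.22) of the crosslinked and 8.70% (8.63 to 8.77) of the live library, and fragments above 400 nt were 7.88% (7.81 to 7.95) and 9.10% (9.02 to 9.17). In the bin from 50 to 59 nt the log2 ratio of shares, crosslinked over live, was -1.05 (-1.09 to -1.01), and in that from 80 to 89 nt it was highest, at 0.19 (0.17 to 0.20), or 1.14-fold. The peak at 68 to 88 nt held 26.9% (26.8 to 27.0) of crosslinked and 25.2% (25.1 to 25.3) of live fragments, and its width at 50% of its height was 16 and 17 nt. Its contrast was 2.42 in crosslinked and 1.88 in live cells, a called difference of 0.54 (0.51 to 0.57) that was 0.35 or 0.18 with window and flanks set 10 nt longer or shorter, with the shorter flank, at 50 to 60 nt, lying inside the range that was lower in crosslinked cells.

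**Figure D3:**
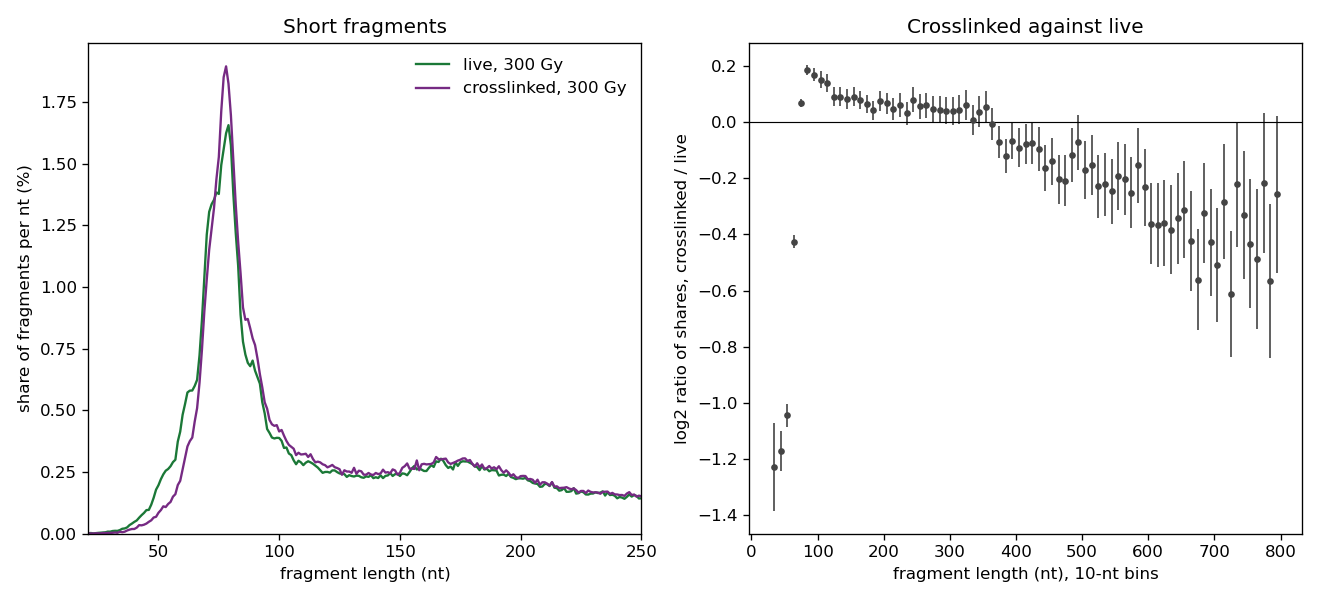
Left, share of fragments per nt (%) against fragment length (nt) from 21 to 250 nt in the live and crosslinked libraries; right, log2 ratio of shares (crosslinked over live) in 10-nt bins, with bars for 95% counting intervals. Crosslinked cells have the higher peak at 78 nt and fewer fragments on its short side, where the ratio is -1.05 at 50 to 59 nt.

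No difference was called at the longer features. At the one-repeat feature the contrasts were 0.43 and 0.44 in crosslinked and live cells (difference -0.0043, -0.031 to 0.026). At the between feature they were 0.10 and 0.12 (difference -0.02, -0.06 to 0.02), and at the two-repeat feature 0.19 and 0.23 (difference -0.04, -0.09 to 0.0046). The intervals allow a two-repeat contrast up to 0.09 lower in crosslinked cells.

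The helical repeat of DNA was sought as a periodicity near 10 nt. Live cells had their best-fitting period at 10.7 nt (95% interval 10.6 to 10.8) with an amplitude of 0.069 (log2), and crosslinked cells at 10.8 nt (10.4 to 12.5) with 0.043. At the period set beforehand the amplitudes were 0.047 (0.040 to 0.054) and 0.033 (0.026 to 0.042), above the upper 95% limit of 0.011 from redraws of a smooth profile of either library. That smooth profile was made with a Gaussian of sigma 10 nt. It also flattens the short peak, whose width at 50% of its height was 17 nt in live and 16 nt in crosslinked cells. Passing the limit thus does not tell a helical periodicity apart from the shape of this peak. The amplitude was higher in live cells by 0.013 (0.0026 to 0.024), a difference under the same limitation. From 100 to 300 nt the amplitudes at that period were 0.011 and 0.0083, against limits of 0.011 and 0.012 for smooth profiles. The best-fitting periods there were 11.2 nt in live cells, with an amplitude of 0.030, and 11.4 nt in crosslinked cells, with 0.020; both amplitudes exceeded the limit of 0.017 for the best period of a smooth profile. In the 4 size-selected libraries, from 60 to 200 nt, amplitudes at the period set beforehand did not exceed the limits for smooth profiles (0.010 against 0.044 in intact replicate 1, 0.025 against 0.063 in replicate 2, 0.043 against 0.055 in the lysed and 0.088 against 0.27 in the 0 Gy library). At their best-fitting periods the amplitudes lay below the limits for the best period of a smooth profile in intact replicate 1 (0.049 against 0.065), the lysed library (0.072 against 0.080) and the 0 Gy library (0.33 against 0.37), and above it in intact replicate 2 (0.096 against 0.092), whose best period, 14 nt, was the longest one fitted.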

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

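Read pairs counted in the file headers but absent from the length tables, which stop at 1000 nt, enter none of the comparisons. In intact size-selected replicate 1 they were 4.53% of pairs (4.50 to 4.57), above the 3.10% of the lysed library and the 1.67% of the 0 Gy library; in replicate 2 they were 1.79%, below the lysed library. The live library had 161 such pairs (0.0288%) and the crosslinked library 87 (0.0164%). These 2 have no control library and are listed only because their counts pass the limit of a count of 0 (0.000537% and 0.000565%), as the counts of all 6 libraries do; with 43 and 30 fragments still present from 970 to 979 nt, some longer pairs are expected, so their presence shows nothing further. The longest pair spanned 1828 nt in the live and 1936 nt in the crosslinked library. It spanned 192447646 and 189218072 nt in intact replicates 1 and 2, 172888646 nt in the lysed and 94334585 nt in the 0 Gy library. How many of the pairs outside the tables are true long fragments was not tested.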

How the results depend on the processing

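Of 89 alternative values, 63 stayed within the spread of the value reported (1 SD between the intact libraries, or the counting interval) or within 1.5 times a count. The other 26 moved further, and no called difference changed direction. Some of the 63 could not have moved. Leaving out 1 of 2 intact libraries shifts their mean by less than 1 SD, and cannot reverse a call that needed both on the same side. A prominence minimum of 0.06 could lose no maximum, as the lowest called prominence was 0.082. These values are thus no evidence of stability. Causes were not tested beyond what each setting's construction shows. The two-repeat difference between intact and lysed cells was 0.22 with narrower windows and 0.15 with windows shifted 10 nt shorter, and 0.20 to 0.21 without either intact library. Against 0 Gy it was 0.25 with narrower windows, 0.21 and 0.10 with windows 10 nt longer and shorter, and 0.20 with summed counts, which is also the value at a floor of 5 fragments per nt, chosen after seeing the data; without either intact library it was 0.22 to 0.23. The one-repeat difference between intact and lysed cells was 0.37 with narrower windows, 0.16 and 0.44 with windows 10 nt longer and shorter, and the uncalled gyre difference was 0.049 and -0.16 with those shifts. Without either intact library the one-repeat difference was 0.33 to 0.36, the gyre difference -0.12 to -0.06, the between difference 0.12 to 0.27 against lysed and 0.57 to 0.71 against 0 Gy cells. The between window shifted 10 nt shorter fell under the depth floor in the 0 Gy library and gave no value. With flanks weighted to the window centre, also chosen after seeing the data, the gyre differences were -0.089 (intact minus lysed) and 0.56 (crosslinked minus live). The crosslinked-minus-live gyre difference was 0.58 with narrower windows and 0.35 and 0.18 with windows 10 nt longer and shorter, and the uncalled two-repeat difference was 0.014 with windows 10 nt shorter. The 0 Gy library had 1 called maximum instead of 2 with smoothing of 3 or 8 nt, and with a trend of 60 nt its second call was at 252 instead of 162 nt. Intact replicate 2 had 2 instead of 3 with smoothing of 3 nt or a trend of 60 nt, which lost the call at 375 nt; crosslinked cells had 2 instead of 3 in the same settings, which lost that at 687 nt, and with smoothing of 8 nt had 366 nt in its place; and intact replicate 1 had 3 instead of 4 with smoothing of 3 or 8 nt or a trend of 60 nt, which lost that at 560 nt. From 100 to 300 nt instead of 60 to 200 nt the periodicity amplitudes at the period set beforehand were 0.011 (live) and 0.0083 (crosslinked). Within 50 to 500 nt the medians were 133 nt (crosslinked), 131 nt (live), 362 and 359 nt (intact replicates 1 and 2), 335 nt (0 Gy) and 361 nt (lysed). No paired analysis was possible because the controls of the size-selected experiment and the libraries of the crosslinking experiment carry no replicate number and have 1 library each. Depth limits the 0 Gy comparison to the between and two-repeat features; the three-repeat feature, with 11.8 fragments per nt in its thinnest flank, was left out of it too.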

Other observations

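The tests in this part were chosen after the profiles had been seen, though the two-repeat and one-repeat windows they use were set before. Inside the short peak, live cells had fine maxima at 61, 71, 79 and 91 nt, crosslinked cells at 61, 70, 78 and 90 nt, and both a further one just above 100 nt, after an 11-nt running mean was subtracted. The spacings ran from 8 to 12 nt with a mean of 10 nt in both libraries. A running mean of that width favours such spacings. How often separate counting noise in 2 libraries would place maxima within 1 nt of each other was not computed. Their shared sharp peak and this filter could also place them so. The largest SD of a position over redraws was 0.82 nt. These redraws start from the observed counts and search within 5 nt of each maximum, so a small SD cannot exclude counting noise. The spacing is near the helical repeat of DNA, but was not told apart from the spacing that the filter favours.

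The excess of 350 to 390 nt fragments in intact over lysed cells is the pattern most worth following. A length preference of the genome sequence or of the ligation is argued against by the contrast of 0.025 in the lysed library, which shares both. That contrast is also part of the difference being explained, so it is not separate evidence. Unequal gel selection stays open. The two-repeat contrasts of the 2 intact libraries differed by only 0.013 (-0.0042 to 0.030), but from 310 to 429 nt the log2 ratio between these libraries ran only from -0.30 to -0.24, too narrow to move a contrast by as much as the 0.20 between intact and lysed cells, so their agreement decides nothing. The live and crosslinked libraries, not selected for long fragments, had contrasts of 0.23 (0.20 to 0.26) and 0.19 (0.15 to 0.22), and the 0 Gy library, selected like the intact ones, had 0.0014 (-0.14 to 0.14). These were looked at after their values were known; the first 2 come from another experiment and were also cut from gels, each of the 3 conditions has 1 library, and none bears on how the lysed library was selected, so they do not settle the question. The state of the chromatin at irradiation is what the design differs in and was not tested further, and 1 lysed library stands for that condition.

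The size-selected controls should hold few fragments near 80 nt, yet both had a short maximum, as did both intact libraries. The positions were not alike. The lysed maximum was at 82 nt (SD 0.71 nt) and those of intact replicates 1 and 2 at 83 and 82 nt, but the 0 Gy maximum was at 72 nt (SD 2.3 nt). Called in the same way, the live and crosslinked maxima were at 74 and 75 nt. At 68 to 88 nt the lysed library held 0.16% and the 0 Gy library 1.63%, against 0.21% and 0.10% in the intact libraries. In the 0 Gy library the ratio of fragments at 50 to 100 nt to those above 100 and up to 150 nt was 3.28 (2.64 to 4.09), an interval that excludes the 1.19 and 1.08 of the 2 size-selected intact libraries, which argues against carry-over from these libraries as its whole source. The live and crosslinked libraries, which were not selected for long fragments, had 2.99 and 2.72, both inside that interval; they come from another experiment and were filtered differently, so carry-over from such libraries stays open and is not shown. Fragments formed in cells without irradiation also stay open and were not tested. In the lysed library the ratio was 1.18, with a 95% interval, up to 1.23, that includes the value of intact replicate 1 and excludes that of replicate 2, so this ratio does not decide whether carry-over was the source there. Fragments from 50 to 100 nt were 0.34% of the lysed library, against 0.43% and 0.21% of intact replicates 1 and 2. Carry-over at all lengths alike, as their whole source, would thus need most lysed fragments to be carried over. The lysed two-repeat contrast, 0.025 (0.011 to 0.038) against 0.24 and 0.22, argues against that. Carry-over of short fragments alone, or as a part of the source, stays open.

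The lower share of fragments under 70 nt and above 400 nt in crosslinked cells cannot be told apart from unequal recovery or gel selection of the 2 libraries. The one-repeat contrast differed by -0.0043. It cancels smooth trends and lies at lengths between those that differed, so it does not bear on the cause. With 1 library for each condition, fixation and library preparation coincide. An effect of fixation on the breaks themselves also stays open and was not tested.

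A maximum at 560 nt in intact replicate 1 invited the question whether a further repeat of the series is visible. At 530 to 580 nt the intact-minus-lysed difference in contrast was 0.017 (-0.0029 to 0.037), with replicate 1 at -0.0096 (-0.031 to 0.012) and replicate 2 at 0.044 (0.022 to 0.068), so the 2 libraries disagree by more than counting error. Flanks weighted to the window centre gave 0.016 (-0.0039 to 0.035) for the mean. A feature 0.5 times as large as that at 350 to 390 nt lies outside these intervals, which hold counting error only; a smaller one is not excluded. Against the 0 Gy library this feature fell under the depth floor, and at the floor of 5 fragments per nt the difference was -0.12 (-0.30 to 0.04).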
